A study of Mus musculus with 2 samples.

How the data were processed

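The series holds 1 Drop-seq library of microdissected arcuate nucleus and median eminence from a pool of 7 WT mice and 1 from a pool of 6 Irx5KO mice, with groups taken from the genotype labels. Live cells were sorted before capture, and only the 3' ends of transcripts were amplified, per the labels' protocols. The submitters' processing notes name bcl2fastq, Picard, STAR 2.6.0b and Seurat 3 and the genome build mm10. The role and settings of each are not given in the sources used here.

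The authors deposited the WT library as UMI counts per gene and barcode, for 2800 barcodes and 28008 genes. The authors deposited the Irx5KO library, and a merged table of both libraries, as natural log values, namely ln of 1 plus the count scaled to 10000 per barcode, as the values show. In the Irx5KO table exp(value) minus 1 summed to 10000 in every barcode, and 100% of values were whole multiples of the barcode's step within 1e-06, so UMI counts were recovered as whole numbers. The same inversion of the merged table gave back the raw WT counts, with 0 of 4276208 compared UMIs differing. The design had assumed raw counts for both libraries, and all values were computed from the raw WT and recovered Irx5KO counts. The Irx5KO table held 2350 barcodes with 212 to 4985 genes and at most 9.93% mitochondrial UMIs, so it had been filtered before deposit. The WT table had not, and 173 of its barcodes were absent from the merged table. The tables shared 25619 genes.

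Cells with at least 500 genes and at most 20% mitochondrial UMIs were kept in both libraries. Doublets were called with the Scrublet method at an expected rate of 5%. In WT 9 of 1850 cells (0.487%) were called, under the 0.5% below which calls were not used, so none was removed. In Irx5KO 24 of 1972 (1.22%) were called and removed. Kept cells had 587 to 17961 UMIs in WT and 587 to 14342 UMIs in Irx5KO. Cells of both libraries were clustered together on 2000 variable genes, 30 principal components and 15 neighbours with the Leiden algorithm at resolution 1, without batch integration, and neuron-like cells were clustered again in the same way.

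Clusters were named from marker lists, and the markers, filters, gene lists and alternatives were fixed before the data were examined, except where stated otherwise. The scoring rule was set after the clusters were seen. The score of a marker set was the mean over its markers of the log2 ratio of CPM plus 10 to the median of clusters. A set could name a cluster with a score of at least 1 and at least 3 markers 2-fold up. Of such sets, the one with most markers among the 10 leading genes gave the name, unless another set had more there or none of its markers there was its own alone. Clusters that failed it stayed unnamed, and the shares of their cells are given per library with the results.

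UMIs were summed over the cells of a class in each library and expressed as CPM. Ratios are given for classes with at least 50 cells in each library and for genes with at least 50 UMIs over both, with exact conditional binomial 95% intervals. Exceptions are Irx5 and its relatives and single genes followed over all classes, whose ratios are given at fewer cells or UMIs, with the same intervals. Sums have exact Poisson intervals and shares exact Clopper-Pearson intervals. A gene at 0 was set against 3 counts. With 1 library per genotype no test between genotypes was made, and genes are counted as at least 1.5-fold apart as a matter of size alone. The median log2 ratio of each of 32 gene lists was placed among 10000 random lists of the same size matched on expression in 20 bins, which describes these libraries and is no test of genotype. Shares of cells with a UMI were taken after thinning each cell to 1000 UMIs, with shallower cells left out.

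Genes were named by a fixed rule in several parts. The first took Irx5 and its relatives. The next took genes at least 1.5-fold apart in the same direction in every class measured, with at least 4 classes at 50 UMIs, up to 10 per direction by the median absolute log2 ratio. The next covered the 4 classes with most cells in the smaller library. It took genes with at least 100 UMIs, at least 10 cells with a UMI in the higher library and at most 20% of that library's UMIs in 1 cell, at least 1.5-fold apart. Up to 12 per direction were ranked by the interval bound nearest to no difference, without class markers and genes of the part before. The last took, per list and in the class where it is described, up to 4 members with the largest such bound, or up to 2 with most UMIs where none was 1.5-fold apart. Of the genes so named, a part is described in the text, and genes that define or lead a cluster of their class have no difference described. Some genes named by the rule are not reported here. Genes outside the rule that are given for more classes were chosen after their values were seen.

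Python 3.11.15, numpy 2.4.6, scipy 1.17.1, scanpy 1.11.5, anndata 0.12.19, igraph 0.11.9 and matplotlib 3.10.9 were used, with R 4.3.3, edgeR 4.0.16 and DESeq2 1.42.0 for the TMM and median-of-ratios scaling alternatives alone. Near-identical transcripts were found with BLAST 2.17.0 in GENCODE vM21 transcripts, at 90% identity over at least 100 bases. By name, 25243 of 26840 genes of the merged table matched this annotation, which is on mm10 and gave the coordinates.

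The ratios and list percentiles were tested on simulated data, with 200 of the genes of a class set apart by known folds and all compared genes of the class drawn, from 496 in microglia-like to 10910 in neuron-like cells. For neuron-like, tanycyte-like, VLMC-like, oligodendrocyte-like, OPC-like and microglia-like cells, 92.4%, 87.3%, 80.9%, 78.8%, 76.6% and 83% of genes set 2-fold apart had an interval that excluded no difference on the right side. Of the genes left alike, 3.37%, 5.33%, 6.97%, 6.58%, 10.9% and 7.43% came out at least 1.5-fold apart by counting error. In the same classes the intervals of 95.9%, 95.7%, 96.9%, 96.4%, 96.1% and 95.6% of such genes included no difference. Counts were drawn as Poisson counts around a mean shared by both libraries, without variation between cells or pools. The shares of intervals that included no difference were thus set by construction. They check the computation alone, and real libraries can vary more.

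Alternatives covered the filters on genes, mitochondrial UMIs and doublets, the merged table, the clustering, the scaling and denominator of the ratios, a mean over cells in place of sums, the UMI minimum and the depth of thinning. Which results count as answering a comparison, and so have each moved value printed, was widened after the results were seen.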

Results

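The arcuate nucleus and the median eminence lie at the base of the hypothalamus and hold neurons that control feeding, growth and reproduction, along with tanycytes, the glia that line the floor of the third ventricle. Cells of this region from adult CD-1 mice aged 7 to 8 weeks were sorted for live cells and profiled by Drop-seq, a droplet method that counts transcripts by unique molecular identifiers (UMIs) at their 3' ends. A pool of 7 wild-type (WT) mice and a pool of 6 mice without Irx5 (Irx5KO), a homeobox transcription factor, gave 1 library each. After filtering, the WT library held 1850 cells and 3985121 UMIs, with a median of 1620.5 UMIs and 1059.5 genes per cell. The Irx5KO library held 1948 cells and 4908128 UMIs, with a median of 1691.5 UMIs and 1123.5 genes. The comparison asks how the cells of this region and their transcripts differ between the genotypes. With 1 library per genotype no difference has a replicate check, and the 95% intervals given with the values cover counting error only.

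Irx5 was counted in the WT library and not in the Irx5KO library. In WT there were 13 UMIs in 11 of 1850 cells, or 3.26 CPM, its UMIs scaled to the library total (95% Poisson interval 1.74 to 5.58). In Irx5KO there were 0 UMIs in 1948 cells, which allows a level of up to 0.611 CPM at 3 counts and up to 0.154% of cells with a UMI, so the level was at least 5.34-fold lower with the WT level as counted. With the counting error of the WT UMIs included, the 95% interval of the ratio starts at 3.75-fold lower. Of the WT UMIs, 5 were in ependymal-like cells and 5 in oligodendrocyte precursor (OPC)-like cells, classes with smaller shares in the Irx5KO library. At the WT level of each class, known from these few UMIs, 7.33 UMIs would be counted in the Irx5KO cells, and within a class no difference was detectable at this depth. Irx5 (ENSMUSG00000031737.11) spans positions 92357625 to 92376286 of chromosome 8 in mm10, on the plus strand, with 3 exons. The deleted part is not given in the sources used here, and a 3' tag outside it would check nothing.

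Irx3, a neighbouring homeobox gene at positions 91798525 to 91802067 of the same chromosome, was lower in Irx5KO over all cells as well. It had 29 UMIs (7.28 CPM) in WT and 4 UMIs (0.815 CPM) in Irx5KO, 8.93-fold lower (95% interval 3.14 to 34.96). Its WT UMIs were also mostly in ependymal-like (16) and OPC-like cells (9). At WT class levels 12.5 UMIs would be counted in Irx5KO. Within ependymal-like cells the interval of 0.493-fold to 18.8-fold lower and within OPC-like cells that of 0.493-fold to 156-fold lower included no difference. Irx1 had 12 UMIs in WT and 15 in Irx5KO, Irx2 had 11 and 9, and Irx6 had 2 and 0, while Irx4 had 0 in both. In OPC-like cells alone Irx1 was at 39.9 CPM in WT and 110.1 CPM in Irx5KO, a ratio of 2.76 (1.11 to 6.899). Fto, the RNA demethylase gene next to Irx3, was at 43.2 CPM in WT and 47.5 CPM in Irx5KO, a ratio of 1.1 (0.899 to 1.35).

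Neuron-like and tanycyte-like cells held larger shares of the Irx5KO library, and ependymal-like, OPC-like and oligodendrocyte-like cells smaller ones. Neuron-like cells were 33.9% of WT cells (627) and 45.9% of Irx5KO cells (895), a ratio of 1.36 (95% interval 1.22 to 1.504). Tanycyte-like cells were 15.4% and 20.8%, a ratio of 1.35 (1.16 to 1.58). Ependymal-like cells, the ciliated cells of the ventricle wall, were 7.24% of WT and 2.16% of Irx5KO cells, 3.36-fold lower (2.36 to 4.87). Expressed as Irx5KO over WT this ratio was 0.298, and it became 0.166 with at least 800 genes per cell, 0.198 at clustering resolution 2 and 0.554 with a marker score per cell in place of clusters. OPC-like cells were 10.2% of WT and 3.95% of Irx5KO cells, 2.59-fold lower (1.97 to 3.41), and oligodendrocyte-like cells were 10.5% and 5.96%, 1.77-fold lower (1.399 to 2.25).

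Among the smaller classes, pars tuberalis-like cells, pituitary tissue around the stalk, were 1.83-fold lower in Irx5KO (1.26 to 2.69) and mural-like cells of vessel walls 1.57-fold lower (1.03 to 2.41). Astrocyte-like cells were few, 14 in WT and 33 in Irx5KO, and 2.24-fold higher (1.17 to 4.53). Microglia-like cells had a ratio of 1.08 (0.748 to 1.57) and vascular leptomeningeal (VLMC)-like cells, the fibroblasts of the meninges, one of 1.05 (0.818 to 1.34). Endothelial-like cells numbered 20 in WT and 14 in Irx5KO, and committed oligodendrocyte precursor (COP)-like cells 19 and 15. With clusters formed without the genes that stood apart between the libraries across classes, the ratio was 1.35 for neuron-like, 1.35 for tanycyte-like, 0.3097 for ependymal-like, 0.387 for OPC-like and 0.565 for oligodendrocyte-like cells. Clusters left without a name held 2.27% of WT and 2.93% of Irx5KO cells. All shares are of cells that passed dissociation and the live-cell sort.

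**Figure D1:**
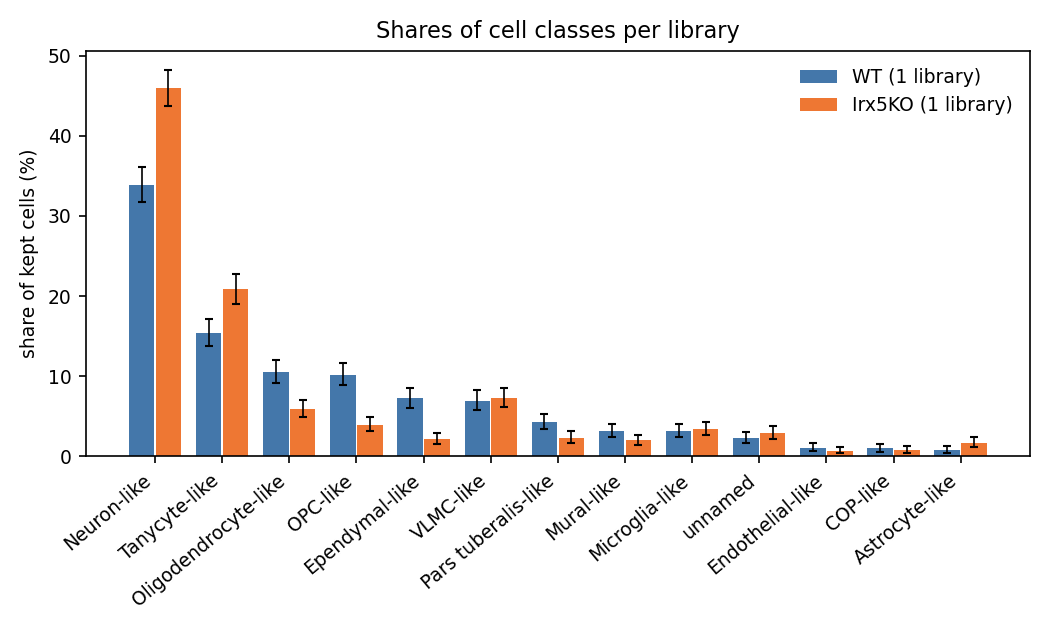
Share of kept cells (percent, vertical axis) in each cell class (horizontal axis) in the WT library (blue) and the Irx5KO library (orange), 1 library each, with exact 95% binomial intervals as error bars. Neuron-like cells made up 33.9% of WT and 45.9% of Irx5KO cells, and ependymal-like cells 7.24% and 2.16%.

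Among neuron-like cells, Agrp-like cells, which drive feeding, and Kndy-like cells, which express kisspeptin and neurokinin B, held larger shares in Irx5KO. Cells like those of the suprachiasmatic nucleus (SCN), the circadian clock nucleus in front of the arcuate nucleus, held a smaller share. Agrp-like cells were 14 of 627 WT neuron-like cells (2.23%) and 45 of 895 Irx5KO neuron-like cells (5.03%), a ratio of 2.25 (95% interval 1.21 to 4.44). Kndy-like cells were 2.71% and 5.14%, a ratio of 1.896 (1.07 to 3.53). SCN-like cells were 16.3% and 7.49%, 2.17-fold lower (1.58 to 3.003). When neuron clusters were formed without the genes that stood apart between the libraries across classes, the Irx5KO over WT ratios were 2.48 for Agrp-like, 2.02 for Kndy-like and 0.424 for SCN-like cells. Ghrh-like cells, which release growth hormone-releasing hormone, were 7.82% of WT and 14.2% of Irx5KO neuron-like cells, but they were not named in that alternative, so these are values without a comparison. GABAergic-like cells of no other named type were 13.4% and 9.05%, 1.48-fold lower (1.08 to 2.03), and were not named in 7 of the alternatives. No type was named for 57.6% of WT and 59.1% of Irx5KO neuron-like cells. In the clustering of all cells, before neuron-like cells were clustered again, the cluster with most WT neuron-like cells was led by Ttr (225 WT and 301 Irx5KO cells) and the cluster with most Irx5KO neuron-like cells by Npvf and Agrp (130 and 311 cells). Ttr had 306 UMIs in all WT and 9 in all Irx5KO neuron-like cells, so it leads the former cluster through WT cells.

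**Figure D2:**
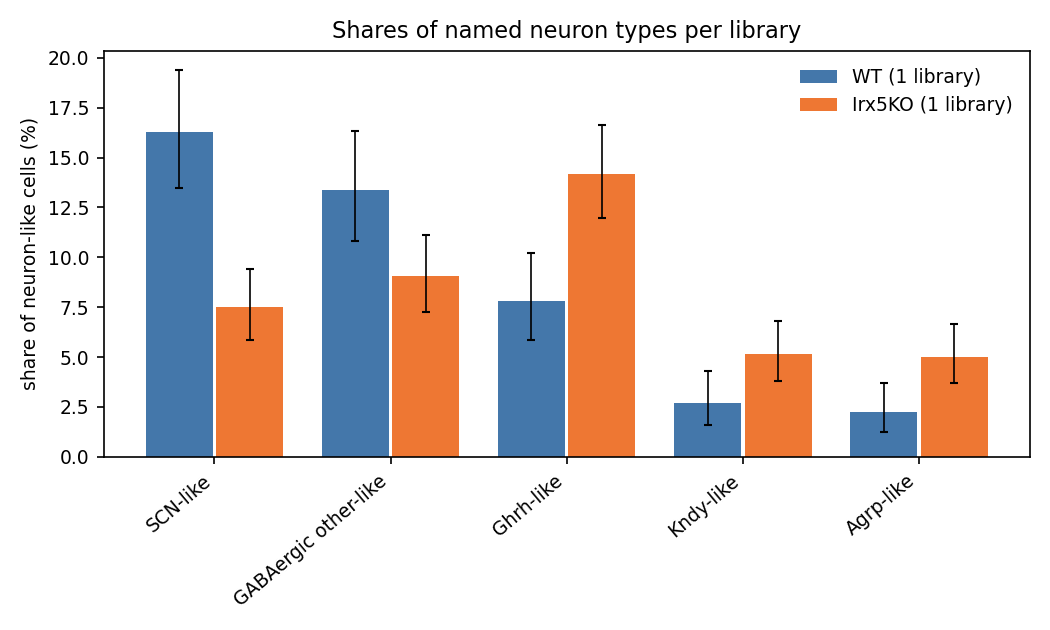
Share of neuron-like cells (percent, vertical axis) of each named type (horizontal axis) in the WT library (blue, 627 cells) and the Irx5KO library (orange, 895 cells), with exact 95% binomial intervals as error bars. SCN-like cells were 16.3% in WT and 7.49% in Irx5KO, and Agrp-like cells 2.23% and 5.03%.

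A small set of genes stood apart in the same direction in every class in which they were measured, and many of them share sequence with pseudogenes. Of 1492 genes measured in at least 4 of the 6 classes compared, 15 were at least 1.5-fold higher and 31 at least 1.5-fold lower in Irx5KO in each of their classes. Hmgb1, a chromatin protein, was 3.38-fold to 5.31-fold lower, and the ribosomal protein gene Rps28 2.29-fold to 2.75-fold lower. The Notch target Hes1 had a median of 2.46-fold lower, the antiproliferative gene Btg1 one of 2.32-fold and the chromatin factor gene Morf4l1 one of 2.47-fold. Eef1a1, the translation elongation factor, was 1.69-fold to 2.33-fold higher, and the splicing factor gene Cwc22 2.22-fold to 3.04-fold higher. The processed pseudogenes Gm10263 (median 5.93-fold lower) and Gm13777 (2.701-fold higher) led each direction. Of these 46 genes, 43 have a near-identical transcript of another gene, so single values for many of them are uncertain. Hes1 has 0 such partners. Over all cells, the log2 ratios alone and summed with partners were -1.01 and -1.004 for Btg1, 1.35 and 1.32 for Cwc22 and 0.996 and 0.98 for Eef1a1. Other genes changed more when summed, with -1.223 and -1.611 for Rps28, -2.482 and -1.615 for Gm10263 and 1.336 and 0.46 for Gm13777. Hmgb1 went from -2.14 to -0.66, and its partners held 11872 UMIs against 1063 of its own. Morf4l1 matched 653 genes with 307223 UMIs, against 2049 of its own, so its sum says little about it.

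Neuron-like cells of the Irx5KO library had less Sez6, a membrane protein gene of neurons, and, as in several other classes, less of the metallothionein gene Mt3 and of genes of oxidative phosphorylation. Of 10910 genes measured, 1360 were at least 1.5-fold higher and 707 at least 1.5-fold lower. The higher part was 65.8%, and 60.2% with TMM or 58.02% with median-of-ratios scaling. Sez6 was at 476 CPM in WT and 81.1 CPM in Irx5KO, 5.87-fold lower (95% interval 5.09 to 6.78). With cells thinned to 1000 UMIs, 31.6% of WT and 7.45% of Irx5KO neuron-like cells had a Sez6 UMI (51.7% and 21.6% unthinned), against 1.64% and 1.23% of tanycyte-like cells. Thinning left out 386 WT and 404 Irx5KO cells. Median depths in WT and Irx5KO were 2126 and 2423 UMIs in neuron-like and 1825 and 1612.5 UMIs in tanycyte-like cells. Mt3, which lies near Irx5 on chromosome 8, was 1.83-fold lower (1.69 to 1.99), and 1.41-fold lower in tanycyte-like (1.29 to 1.54) and 2.13-fold lower in OPC-like cells (1.59 to 2.92), while Bbs2, a cilium gene of the same stretch, was 2.14-fold higher (1.32 to 3.595). The insulin-like growth factor receptor gene Igf1r was 1.89-fold higher (1.22 to 3.03) and the leptin pathway gene Stat5b 1.55-fold higher (0.965 to 2.56), the 2 genes at least 1.5-fold apart among 15 measured genes of leptin and insulin signalling (median log2 ratio 0.11, percentile 56.6, and 0.38 as a mean over cells). Both were under 1.5-fold apart in at least 1 alternative, inside these intervals.

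Of 23 measured feeding peptides and receptors in neuron-like cells, 7 were at least 1.5-fold higher and 6 at least 1.5-fold lower. Their median log2 ratio was 0.15 (percentile 95.5 among random lists), and 0.40 with at least 800 genes per cell. The peptide genes Agrp, Npy, Ghrh, Pomc, Penk and Avp lead neuron clusters, so their single ratios are not given as differences. The 35 nuclear genes of oxidative phosphorylation had a median of -0.22 (percentile 0.1). Of these 4 were at least 1.5-fold lower and 1 higher, with Cox7c, one of the genes apart in every class, 2.02-fold, Cox5b 1.67-fold and Ndufa1 1.65-fold lower and Atp5g1 2.27-fold higher. The same list was also low in tanycyte-like (median -0.17, percentile 1.2), oligodendrocyte-like (-0.19, percentile 1.9) and OPC-like cells (-0.28, percentile 0.2), but lay within the central 95% of random lists in VLMC-like (-0.15, percentile 9.6) and microglia-like cells (0.035, percentile 31.8). Cox7c and Atp5k of this list are among the genes apart in every class. Both have near-identical transcripts of other genes, so their single values are uncertain. The median of this list in neuron-like cells was not computed with neuron clusters weighted alike. For the 9 measured members of the list of mitochondrially encoded genes, which holds no transfer RNA genes, the median was -0.28 (percentile 1.5). Of these members mt-Cytb was 1.18-fold and mt-Rnr2 1.34-fold lower, and none was 1.5-fold apart. Ribosomal protein genes had a median of -0.16 (percentile 0.5), and 7 of 39 were at least 1.5-fold lower and 1 higher, with Rpl26 (3.57-fold) and Rps29 (2.87-fold) among the lower ones, values that are uncertain because such genes have pseudogenes.

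Immediate early genes, which respond to activity and to tissue dissociation, had a median log2 ratio of -0.22 in neuron-like cells (percentile 0.7), with Jun 1.62-fold lower (1.48 to 1.79) and the other 14 measured genes under 1.5-fold apart. As a mean over cells the median turned to 0.15, and the log2 ratio of Jun, -0.70, became -0.31, under 1.5-fold. Heat shock genes had a median of 0.038 (percentile 75.9), and 3 of 14 were at least 1.5-fold lower, Dnajb1 1.91-fold, Hspa1a 1.71-fold and Cryab 2.42-fold. The log2 ratio of Hspa1a, -0.77, was -0.54 as a mean over cells, under 1.5-fold. Haemoglobin Hbb-bs, a transcript of red blood cells, was 5.699-fold lower (4.16 to 7.93) and the mitochondrial transfer RNA gene mt-Tm 5.68-fold lower (4.13 to 7.92). Hbb-bs was lower in every other class followed as well. It was 1.96-fold lower in tanycyte-like (1.31 to 2.95) and 10.7-fold lower in ependymal-like cells (1.82 to 434). In endothelial-like cells it had 237 UMIs in WT and 0 in Irx5KO. Hlf, a clock output gene, was 1.64-fold lower, but its log2 ratio of -0.71 was -0.46, under 1.5-fold, with neuron clusters weighted alike. The ribosomal protein gene Rpl29 had 6 UMIs in WT and 152 in Irx5KO neuron-like cells, a value that is likewise uncertain, since ribosomal protein genes have pseudogenes and a sharing of its reads was not tested.

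Transcripts of growth hormone (Gh) and prolactin (Prl), hormones of the anterior pituitary, were counted in neuron-like cells of the Irx5KO library. Gh had 1 UMI in WT and 172 in Irx5KO, a ratio of 101 (95% interval 17.9 to 4012), and Prl had 1 and 126, a ratio of 73.98 (13.04 to 2945). They were not limited to neurons, since Gh and Prl together were at 96.7 CPM in neuron-like and 113 CPM in all other Irx5KO cells. With cells thinned to 1000 UMIs, 0% of WT and 6.14% of Irx5KO neuron-like cells had a Gh UMI (0.1595% and 15.9% unthinned), against 0% and 8% of oligodendrocyte-like cells, a class that should lack the gene, so the share is not read as expression by neurons. Median depths in WT and Irx5KO were 2126 and 2423 UMIs in neuron-like and 1855 and 1737.5 UMIs in oligodendrocyte-like cells. The log2 ratio of Gh was 6.66, and 2.16 with at least 200 genes, 1.54 with at least 800 genes, 2.08 with a mitochondrial limit of 10% and 2.08 with doublets kept. For Prl it was 6.21, and 2.10, 1.57, 1.97 and 1.97 in the same settings. These ratios rest on few WT UMIs, since WT neuron-like cells held 2 Gh and Prl UMIs together while 1 unnamed WT cell held 41. Whether that cell was counted as neuron-like in those settings was not tested. Of 6 measured pituitary genes 3 were at least 1.5-fold higher and 2 lower. Their median log2 ratio of 0.83 (percentile 100) turned to -0.16 with at least 200 genes, -0.19 with at least 800 genes and -0.17 with doublets kept.

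**Figure D3:**
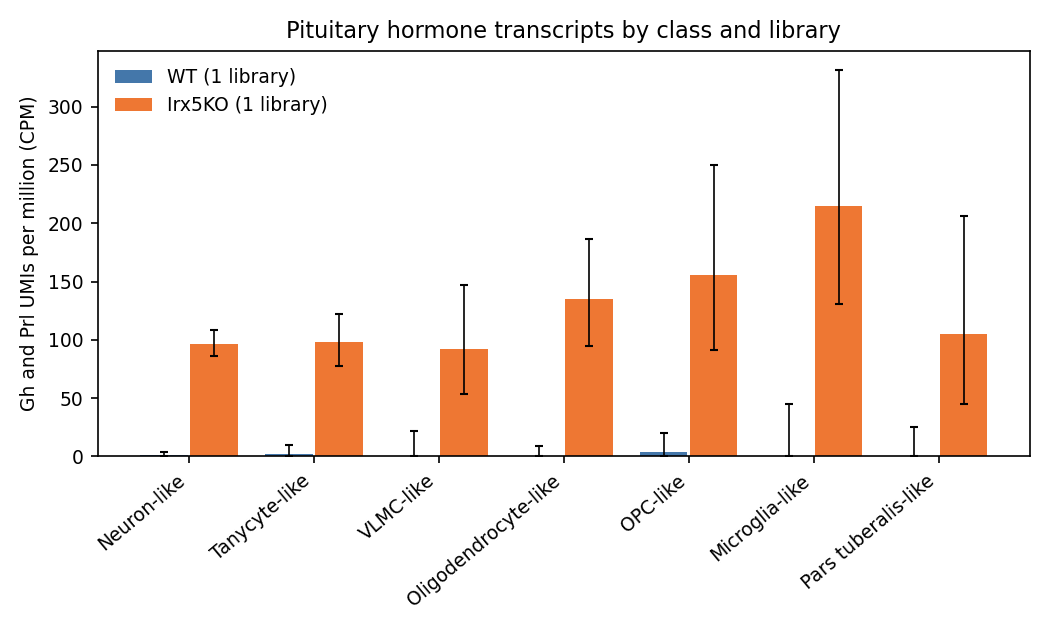
Gh and Prl level (CPM, vertical axis) by cell class (horizontal axis) in the WT library (blue) and the Irx5KO library (orange), 1 library each, with exact 95% Poisson intervals as error bars. In Irx5KO the level was 96.7 CPM in neuron-like, 97.97 CPM in tanycyte-like and 135 CPM in oligodendrocyte-like cells.

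Tanycyte-like cells of the Irx5KO library had more Sparcl1, Ecel1 and Tgfb2 and less Slco1c1, Igfbp5, Sox4 and Dnajb1. Of 5512 genes measured, 568 were at least 1.5-fold higher and 443 at least 1.5-fold lower. The higher part was 56.2%, and 49.3% with median-of-ratios scaling, which turned the balance. Sparcl1, a matrix protein gene, was 5.55-fold higher (95% interval 4.14 to 7.59) and the peptidase gene Ecel1 6.44-fold higher (3.44 to 13.3). Sparcl1 and the glutamate transporter gene Slc1a2 (1.997-fold higher, 1.64 to 2.44) also lead the astrocyte-like cluster, whose share was 2.24-fold higher in Irx5KO. The log2 ratio of Sparcl1 was 2.47, and 1.67 with doublets kept, 1.56 in the merged table and 1.57 with called doublets removed in both libraries. With thinned cells, 7.38% of WT and 24.9% of Irx5KO tanycyte-like cells had a Sparcl1 UMI (10.5% and 30.5% unthinned), against 2.42% and 4% of oligodendrocyte-like cells, whose median depths were 1855 and 1737.5 UMIs. Sparcl1 was also 2.302-fold higher in ependymal-like cells (1.898 to 2.79), while its ratios in astrocyte-like and neuron-like cells are not given, since it leads a cluster of each.

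Slco1c1, a thyroid hormone transporter gene at positions 141524368 to 141570177 of chromosome 6, had 60 UMIs in WT and 9 in Irx5KO tanycyte-like cells and was 9.13-fold lower (95% interval 4.504 to 20.9). It also leads the endothelial-like cluster, which held 1.08% of WT and 0.719% of Irx5KO cells. Of 24 measured tanycyte identity genes, 2 were at least 1.5-fold higher, the growth factor gene Tgfb2 (2.07-fold) among them, and 3 lower, among them Slco1c1 and the growth factor-binding protein gene Igfbp5 (1.82-fold). Their median log2 ratio was 0.16 (percentile 98.7). Of 17 measured progenitor genes, 2 were higher, the fatty acid-binding protein gene Fabp7 (2.68-fold) and the receptor gene Notch1 (1.52-fold), and 2 lower, the transcription factor genes Sox4 (2.62-fold) and Hes1 (1.97-fold), with a median of 0.023 (percentile 60.5). Notch1 was under 1.5-fold apart in at least 1 alternative. Aqp4, the astrocyte water channel gene, was 1.52-fold higher (1.01 to 2.33), but its log2 ratio of 0.60 turned to -0.19 with doublets kept, -0.20 in the merged table, -0.15 with called doublets removed in both libraries and -0.0018 with at least 800 genes. Stress response genes were among those lower, with the heat shock gene Dnajb1 3.02-fold (2.53 to 3.6), and the immediate early genes Atf3 2.64-fold and Klf6 2.38-fold lower. With thinned cells, 25% of WT and 12.3% of Irx5KO tanycyte-like cells had a Dnajb1 UMI (36.1% and 18.2% unthinned), against 4.48% and 0% of OPC-like cells (0 of 57 Irx5KO cells, an upper limit of 6.27%), whose median depths were 1272 and 1327 UMIs. The mitochondrial ribosomal RNA gene mt-Rnr2 was 2.13-fold lower (2.05 to 2.21).

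VLMC-like cells of the Irx5KO library had more of the metallothionein genes Mt1 and Mt2, of H2-D1, B2m, Mgp and Col4a1, and less Gadd45g, Maf and Hspa1a. Of 1348 genes measured, 165 were at least 1.5-fold higher and 203 at least 1.5-fold lower. The higher part was 44.8%, and 61.2% with median-of-ratios scaling, which moved all log2 ratios by 0.12. Mt2 was at 88.1 CPM in WT and 1669 CPM in Irx5KO, 18.9-fold higher (95% interval 11.3 to 34.3), and its log2 ratio of 4.24 became 5.37 with at least 800 genes. Mt1 was 8.07-fold higher (5.92 to 11.2). Both lie on chromosome 8, the chromosome of Irx5, at positions 94172664 to 94173568 (Mt2) and 94179082 to 94180327 (Mt1). With thinned cells, 5.75% of WT and 27.9% of Irx5KO VLMC-like cells had an Mt2 UMI (9.302% and 28.2% unthinned), against 2.34% and 3.92% of neuron-like cells. Median depths of VLMC-like cells were 1174 and 1084 UMIs. The matrix Gla protein gene Mgp was 2.83-fold, the collagen gene Col4a1 2.298-fold and the protease inhibitor gene Timp3 1.83-fold higher. The class I antigen presentation gene H2-D1 was 2.19-fold and its partner B2m 1.96-fold higher.

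Among the genes lower in Irx5KO VLMC-like cells were Gadd45g, a stress-induced gene, 3.26-fold lower (2.58 to 4.17), the transcription factor gene Maf (3.61-fold) and thrombomodulin Thbd (3.698-fold). The stress genes Hspa1a, Ppp1r15a and Dnaja1 were 2.56-fold, 2.41-fold and 2.39-fold lower. Hspa1a was 2.04-fold higher in microglia-like cells (1.69 to 2.47), and of 12 measured heat shock genes in VLMC-like cells 4 were at least 1.5-fold lower and 0 higher (median log2 ratio -0.26, percentile 6.1). With thinned cells, 64.4% of WT and 26.7% of Irx5KO VLMC-like cells had a Gadd45g UMI (68.99% and 35.2% unthinned), against 5.97% and 5.26% of OPC-like cells. Of 6 measured glucocorticoid response genes 2 were higher, Mt1 and Mt2, and 2 lower, the receptor gene Nr3c1 (1.54-fold, and under 1.5-fold in at least 1 alternative) among them. Their median log2 ratio was -0.14 (percentile 27.6), and 3.63 over the genes left with at least 200 UMIs. Of 2 measured endothelial genes 1 was higher, Itm2a, a marker of endothelial-like cells (2.48-fold), with a median of 0.92 (percentile 99.3).

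Oligodendrocyte-like cells of the Irx5KO library had more Sgk1, Olig1 and Olig2 and more cholesterol synthesis transcripts, and less Jun, Fos, Dnajb1 and Hspa1a. Of 2450 genes measured, 229 were at least 1.5-fold higher and 265 at least 1.5-fold lower. The higher part was 46.4%, against 30.1% with TMM scaling and 30.3% with median-of-ratios scaling, each of which moved all log2 ratios by -0.10. The kinase gene Sgk1 was 8.25-fold higher (95% interval 5.14 to 13.9). With thinned cells, 3.03% of WT and 24% of Irx5KO oligodendrocyte-like cells had an Sgk1 UMI (10.3% and 38.8% unthinned), against 1.75% and 1.57% of neuron-like cells. The lineage transcription factor genes Olig2, also a marker of OPC-like cells, and Olig1 were 3.09-fold (2.17 to 4.45) and 1.86-fold higher, and the chloride transporter gene Slc12a2 1.84-fold. Of 10 measured cholesterol synthesis genes 3 were at least 1.5-fold higher, Insig1 (1.702-fold), Cyp51 (1.61-fold) and Pmvk (1.51-fold), and none lower (median log2 ratio 0.45, percentile 99.6), and each of the 3 was under 1.5-fold apart in at least 1 alternative. The 18 myelin genes had a median of 0.030 (percentile 88.5). Dcaf17, a ubiquitin ligase adaptor gene, was 3.34-fold lower (2.22 to 5.203), and 17.6% of WT and 8% of Irx5KO thinned cells had a Dcaf17 UMI (28.7% and 17.2% unthinned), against 2.87% and 0.923% of tanycyte-like cells. Jun was 2.39-fold, Fos 1.87-fold, Dnajb1 2.44-fold, Hspa1a 1.98-fold and the calcium-binding protein gene S100b 2.1-fold lower.

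OPC-like cells had 133 genes at least 1.5-fold higher and 250 at least 1.5-fold lower in Irx5KO of 1721 measured. The higher part was 34.7%, and 13.2% with TMM or 14.2% with median-of-ratios scaling, each of which moved all log2 ratios by -0.17. Among 14 measured genes of the lineage 2 were higher, both markers of the class, and 2 lower, the transcription factor gene Nkx2-2 (2.33-fold, 95% interval 1.14 to 5.37) and the kinase gene Fyn, a marker of COP-like cells (1.64-fold, 0.903 to 3.18, and under 1.5-fold in at least 1 alternative), with a median of 0.10 (percentile 90.5).

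Microglia-like cells, the immune cells of the brain, had more antigen presentation transcripts in the Irx5KO library. Of 496 genes measured, 91 were at least 1.5-fold higher and 71 at least 1.5-fold lower. The higher part was 56.2%, against 77.4% with median-of-ratios scaling, which moved all log2 ratios by 0.20. Of 7 measured antigen presentation genes 6 were at least 1.5-fold higher and none lower. Their median log2 ratio was 0.83 (percentile 99.7), and 1.66 with at least 200 genes and 0.17 as a mean over cells. The class I genes H2-K1 and H2-D1 were 4.04-fold (95% interval 2.58 to 6.56) and 3.16-fold (2.38 to 4.24) higher. The class II genes H2-Aa and H2-Ab1 were 1.87-fold (1.47 to 2.39) and 1.78-fold (1.33 to 2.41) higher. As a mean over cells the log2 ratios of H2-Aa and H2-Ab1, 0.90 and 0.83, became 0.17 and -0.027, and with at least 200 genes 2.02 and 2.47. Of 20 measured genes of microglial state 8 were higher and 1 lower (median 0.47, percentile 99.3), a list that also holds genes that define the class. The lipoprotein gene Apoe was 2.27-fold higher (2.04 to 2.53), and its log2 ratio of 1.18 was 0.37 with at least 800 genes.

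Most gene lists did not stand apart from random lists. Of 32 lists, 29 had a measured member in the class where they are described, and 19 of these had percentiles among random lists from 17.7 to 95.5, inside the central 95%, with medians from -0.14 to 0.22 on the log2 scale. In neuron-like cells these included synaptic vesicle genes (median 0.12, percentile 93.7), GABA and glutamate transmission (0.083, percentile 77.8), glycolysis (0.12, percentile 88.7), the circadian clock (0.031, percentile 35.1), the unfolded protein response (0.068, percentile 64.8), the Irx family with the Fto locus (0.019, percentile 40.2) and the genes near Irx5 (0.019, percentile 36.8). In tanycyte-like cells they included thyroid hormone handling (0.041, percentile 62.5), fatty acid handling (0.22, percentile 91.5), astrocyte genes (0.15, percentile 93.7) and Wnt, Shh, Fgf and Bmp signalling (-0.10, percentile 17.7), with Tcf7l2 1.65-fold lower. Sex-linked genes in neuron-like cells had a median of -0.031 (percentile 30.9), and the Y-linked genes Ddx3y and Eif2s3y were 1.05-fold higher and 1.096-fold lower in Irx5KO. Interferon response genes in microglia-like, haemoglobin genes in VLMC-like and abundant neuropeptides in oligodendrocyte-like cells had 0 measured members.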

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

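The tests of the share of pseudogenes, of transcript length, of the summed folds by direction and of the spread of arcuate types were chosen only after the results were seen, as were the resampled interval of the summed folds, the comparison of Gh and Prl by class, the bound of the arcuate test and the limit of that pattern to Agrp-like, Kndy-like and SCN-like cells.

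Signals above those of the compared cells appeared in barcodes that the merged table leaves out and in cells of no named class. The 173 WT barcodes that are absent from the merged table held Pomc, Gh and Prl at 6567 CPM, against 102 CPM in the other WT barcodes. The 99 cells of the unnamed clusters held the epithelial genes Krt5, Krt14, Krt18 and Epcam at 4088 CPM, against 25.6 CPM in all other kept cells.

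In the set of 46 genes apart in the same direction in every class measured, reads moving between near-identical copies were argued against as the whole cause for the lower genes, since the 28 with copies, in 17 families, had a median fold when summed with them of 1.83 (95% interval over resampled families 1.56 to 2.45), with 5 under 1.5-fold and 1 of these in the other direction, while the median over both directions was 1.67 (1.53 to 1.89). For the 15 higher genes this stays open, with a median fold of 1.38 (1.15 to 1.79) and 9 of them under 1.5-fold when summed, 3 of these in the other direction. Among the lower genes under 1.5-fold when summed, Morf4l1, Usmg5 and Rpl37a matched 653, 597 and 509 genes. Their sums hold mostly UMIs of those other genes, so they say little about copies of these genes. A difference with no tie to pseudogenes was also argued against, since 47.7% of the genes matched to the annotation were pseudogenes (32.5% to 63.3%), against 10.7% of all genes measured in as many classes. Transcript length bias stayed undecided: among ribosomal protein genes outside the set the shorter minus the longer transcripts had a median log2 ratio of -0.23 (-0.57 to 0.061), a first run with genes of the set gave -0.47 (-1.05 to -0.047), and the lower genes of the set were 0.818 times as long as the higher ones (0.456 to 1.24). A different loss of reads that match several places was not tested, and genotype stays open.

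For Gh and Prl in Irx5KO neuron-like cells, a hypothesis is that they came as free RNA from pituitary cells in the Irx5KO suspension. The ratio of their CPM in the other Irx5KO cells to that in neuron-like cells was 1.17 (95% interval 0.977 to 1.404), which met the prediction written before this test. The hypothesis stays open because of the comparison by class, which was added later. There 1 of 11 other named classes, microglia-like cells at 215 CPM (131 to 331), lay apart from neuron-like cells at 96.7 CPM (86.03 to 108). No allowance was made for the number of classes compared. A few cells holding pituitary RNA were argued against, since the 5 cells with most Gh and Prl UMIs held 7.38% of the UMIs. Pars tuberalis-like cells were 1.83-fold lower in Irx5KO, and an unnamed cluster whose best marker set was that of the pituitary held 24 WT and 23 Irx5KO cells, while another unnamed cluster, led by Krt5, whose best set was that of the pars tuberalis, held 18 and 34. The deposited tables were filtered unlike. Of 13 WT barcodes inside the gene and mitochondrial limits but absent from the merged table, 11 held at least 5 UMIs of Pomc, Cga, Lhb, Gh and Prl together. Whether such barcodes had been taken out of the Irx5KO table before deposit is not known, so these cell numbers may not be alike in kind. How much pituitary tissue was taken and how much of its RNA was released stay open, as does genotype.

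The larger shares of Agrp-like and Kndy-like cells and the smaller share of SCN-like cells among Irx5KO neuron-like cells were weighed last. Depth was argued against, since with cells thinned to 1000 UMIs the ratio of Agrp-like and Kndy-like to SCN-like cells was 4.05-fold higher in Irx5KO (2.26 to 7.34). More arcuate and less neighbouring tissue in the Irx5KO pool would raise both arcuate types alike, and the larger over the smaller of their ratios was 1.19 (0.485 to 2.94), an interval too wide to decide. Tissue sampling and genotype cannot be told apart, because each genotype is 1 pool from its own dissections.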

How the results depend on the processing

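The settings with called doublets removed in both libraries, another clustering seed, neuron clusters weighted alike, list medians in the merged table, and neuron types clustered without the genes apart across classes or on thinned cells were chosen after seeing the data. Each genotype has 1 library, so a value counts as moved when it leaves its counting interval, and a count of genes when it moves over 1.5 times. The WT level of Irx5 and the ratio of Irx3 stayed inside these limits in 10 of 10 values, class and type shares in 189 of 195, list medians in 249 of 260, gene ratios in 2554 values, counts of genes in 12 of 30 and shares of cells with a UMI in 13 of 32. Of the rest, 64 gene ratios moved and 9 turned, and 7 list medians moved and 4 turned. Astrocyte-like cells were not named in 4 alternatives, GABAergic-like cells of no other type in 7 and Ghrh-like cells in 2, and no endothelial gene was measured in VLMC-like cells at 200 UMIs. Depth limits the small classes most, where few genes reached 50 UMIs. For the values that moved or turned below, the cause was not tested unless one is given.

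With at least 800 genes per cell the Irx5KO over WT share ratio was 0.166 for ependymal-like, 1.22 for neuron-like and 1.13 for tanycyte-like cells. The ependymal-like ratio was 0.203 at resolution 0.5, 0.198 at resolution 2 and 0.554 with a marker score per cell.

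With at least 800 genes the log2 ratio of Pomc, which leads a neuron type cluster, was -2.38 in neuron-like cells, against 1.45 as first computed, and that of Aqp4 in tanycyte-like cells -0.0018. The list medians were 0.40 for feeding peptides and receptors and -0.19 for pituitary genes. With at least 200 genes Pomc was at -0.51, the pituitary median at -0.16 and the antigen presentation median in microglia-like cells at 1.66. With a mitochondrial limit of 10% Pomc was at -0.51. With doublets kept Pomc was at -0.53, Aqp4 at -0.19 and the pituitary median at -0.17. Aqp4 was at -0.20 in the merged table and -0.15 with called doublets removed in both libraries.

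As a mean over cells H2-Ab1 in microglia-like cells was at -0.027. The medians were 0.17 for antigen presentation and, in neuron-like cells, 0.37 for feeding peptides and receptors, 0.15 for immediate early genes and 0.38 for leptin and insulin signalling. At 20 UMIs the pituitary median was 0.21, with more genes measured, and at 200 UMIs the glucocorticoid median in VLMC-like cells was 3.63, with fewer.

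The number of genes at least 1.5-fold apart depended on the UMI minimum. In neuron-like, tanycyte-like, VLMC-like, oligodendrocyte-like, OPC-like and microglia-like cells it was 3547, 2679, 1292, 1667, 1618 and 631 at 20 UMIs and 11325, 9986, 9989, 10633, 10292 and 8991 without a minimum, where more genes are tested, and 550, 126, 49, 53, 19 and 27 at 200 UMIs, where fewer are.

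Thinning to another depth moves shares of cells with a UMI by its construction. At 500 UMIs, 20.1% of WT and 3.69% of Irx5KO neuron-like cells had a Sez6 UMI and 3.58% of Irx5KO ones a Gh UMI. In tanycyte-like cells 18.95% and 5.91% had a Dnajb1 UMI and 2.81% and 17.2% a Sparcl1 UMI. In WT 11.8% of oligodendrocyte-like cells had a Dcaf17 UMI and 44.96% of VLMC-like cells a Gadd45g UMI. Without thinning the WT and Irx5KO shares were 51.7% and 21.6% for Sez6, 28.7% and 17.2% for Dcaf17, 10.3% and 38.8% for Sgk1 and 36.1% and 18.2% for Dnajb1. In Irx5KO alone they moved to 15.9% for Gh and 30.5% for Sparcl1.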

Other observations

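The values in this part were chosen after the data were seen, and no explanation of them was tested. Mt1 and Mt2 are metal-binding metallothionein genes. In endothelial-like cells Mt1 was 12.97-fold higher in Irx5KO (7.92 to 22.5) and Mt2 17.1-fold higher (8.27 to 40.8), over 20 WT and 14 Irx5KO cells. In tanycyte-like cells they were 1.11-fold (1.04 to 1.18) and 1.18-fold lower (1.06 to 1.3), and in ependymal-like cells Mt1 was 1.06-fold lower (0.924 to 1.22). In astrocyte-like cells Mt1 was 3.02-fold (1.91 to 5.02) and Mt2 1.17-fold higher (0.648 to 2.22), the latter an interval that includes no difference, and in oligodendrocyte-like cells Mt1 was 1.37-fold lower (1.196 to 1.57) and Mt2 1.62-fold higher (1.103 to 2.37). Mt1 was 1.301-fold higher in pars tuberalis-like cells (1.12 to 1.51) and 1.63-fold lower in mural-like cells (0.729 to 4.01), an interval that includes no difference. Among 4 measured genes near Irx5 on its chromosome, Mt1 and Mt2 among them, the median log2 ratio in VLMC-like cells was 1.81 (percentile 100), with 3 of 4 at least 1.5-fold higher and 0 lower, while the percentiles of this list were 36.8 in neuron-like, 9.1 in tanycyte-like, 57.3 in oligodendrocyte-like, 7.9 in OPC-like and 21.5 in microglia-like cells. Mt1 and Mt2 lie close together and were already named as higher in VLMC-like cells. The VLMC-like median thus largely restates these genes and cannot show a difference along the chromosome. The class I gene H2-D1 was 1.88-fold higher in endothelial-like (1.26 to 2.82), 1.94-fold in ependymal-like (1.24 to 2.97) and 1.73-fold in OPC-like cells (1.27 to 2.35). In neuron-like cells it was 1.18-fold higher (1.01 to 1.37). Its intervals in oligodendrocyte-like (0.755 to 2.1), mural-like (0.614 to 2.055) and pars tuberalis-like cells (0.663 to 1.78) included no difference. Its partner B2m was 1.6-fold higher in endothelial-like cells (1.16 to 2.21). In ependymal-like cells B2m was 1.04-fold higher (0.5465 to 1.87) and in OPC-like cells 1.16-fold lower (0.802 to 1.7), intervals that include no difference. Antigen presentation genes in VLMC-like cells had a median log2 ratio of 0.96 (percentile 99.9), with 4 of 6 at least 1.5-fold higher and 0 lower.

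Other lists stood apart in classes other than those where they were set to be described. Immediate early genes had a median log2 ratio in tanycyte-like cells of -0.45 (percentile 0), with 0 of 20 at least 1.5-fold higher and 5 lower, and in oligodendrocyte-like cells of -0.77 (percentile 0), with 0 of 10 at least 1.5-fold higher and 6 lower. Heat shock genes had a median in oligodendrocyte-like cells of -0.50 (percentile 0), with 0 of 13 at least 1.5-fold higher and 5 lower, and in OPC-like cells of -0.39 (percentile 0.7), with 0 of 10 at least 1.5-fold higher and 3 lower. Cholesterol synthesis genes in tanycyte-like cells had a median of 0.46 (percentile 97.7), with 4 of 9 at least 1.5-fold higher and 0 lower. Glucocorticoid response genes in oligodendrocyte-like cells had a median of 0.41 (percentile 99.1), with 4 of 8 at least 1.5-fold higher and 1 lower. Progenitor genes in OPC-like cells had a median of -0.55 (percentile 0.2), with 0 of 11 at least 1.5-fold higher and 4 lower. Myelin genes in neuron-like cells had a median of -0.39 (percentile 0.1), with 0 of 11 at least 1.5-fold higher and 3 lower, beside oligodendrocyte-like shares of 10.5% in WT and 5.96% in Irx5KO, and in tanycyte-like cells of -0.42 (percentile 1.0), with 1 of 7 at least 1.5-fold higher and 2 lower. Feeding peptides and receptors in tanycyte-like cells had a median of 0.53 (percentile 98.7), with 3 of 6 at least 1.5-fold higher and 0 lower, and abundant neuropeptides there of 0.73 (percentile 98.3), with 2 of 4 at least 1.5-fold higher and 0 lower. The latter list was set as peptides that leak as free RNA. Npy, on both lists, had 7 UMIs in WT and 51 in Irx5KO tanycyte-like cells. It had 7 and 15 in oligodendrocyte-like and 818 and 4092 in neuron-like cells. Whether the tanycyte-like values come from leaked RNA was not tested. Astrocyte genes in VLMC-like cells had a median of 0.61 (percentile 99.3), with 3 of 6 at least 1.5-fold higher and 2 lower, and in oligodendrocyte-like cells precursor genes had one of 0.41 (percentile 99.4), with 2 of 6 at least 1.5-fold higher and 0 lower and ribosomal protein genes one of -0.23 (percentile 0.5), with 1 of 30 at least 1.5-fold higher and 8 lower. Pituitary genes in microglia-like cells had a median of -3.81 (percentile 0.1), with 0 of 3 at least 1.5-fold higher and 3 lower, but 389 of the 391 WT Cga UMIs and all 109 WT Lhb UMIs were each in 1 cell. Mitochondrially encoded genes had a median in tanycyte-like cells of -0.33 (percentile 1.1), with 0 of 9 at least 1.5-fold higher and 2 lower, in oligodendrocyte-like cells of -0.34 (percentile 1.1), with 0 of 8 at least 1.5-fold higher and 0 lower and in microglia-like cells of -0.61 (percentile 0.3), with 0 of 8 at least 1.5-fold higher and 5 lower. Haemoglobin genes in neuron-like cells had a median of -2.64 (percentile 0), with 0 of 2 at least 1.5-fold higher and 2 lower.

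The unnamed clusters differed in their epithelial genes. The 47 cells of the cluster led by Bpifa1 and Cldn4, whose best marker set was that of the pituitary with 5 of 6 markers 2-fold up but none among its leading genes, had Krt18 at 1904 CPM and Epcam at 2986 CPM, and the 52 cells of the cluster led by Krt5 had Krt5 at 789 CPM, Krt14 at 456 CPM and Epcam at 1208 CPM. All 150 Bpifa1 UMIs of the former cluster were in 1 cell. In the unnamed WT cells, 41 Gh and Prl UMIs were in 1 cell. Of the 173 WT barcodes absent from the merged table, 80 had 200 or fewer genes and 2 had more genes than any barcode of the merged table. Another 78 had at least 10% mitochondrial UMIs, and of the other 13, 11 held at least 5 UMIs of Pomc, Cga, Lhb, Gh and Prl together.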
